A study of Mus musculus with 9 samples.

How the data were processed

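Gene expression was measured in brown adipose tissue (BAT), the heat-producing fat depot of mammals, from untreated wild-type C57Bl6J mouse embryos at embryonic days 14.5, 15.5 and 16.5. The stages are written E14.5, E15.5 and E16.5. Each stage had 3 arrays, and the series design text states that each array held an independent preparation pooling the BAT of 3 embryos, so the replicates are separate pools and the total was 9 arrays. RNA was isolated with a column kit for small amounts, labelled with biotin through the WT PLUS reagents and hybridised to MoGene-2_0-st arrays, per the labels' protocols.

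The deposited table held log2 expression values made by the authors with Partek 7.0 and RMA, per the submitters' processing notes. RMA corrects the background, brings probe values of the arrays to a common distribution and summarises the probes of a feature. The table had 30915 entries, each with a gene symbol of its own. How transcript clusters were summarised to 1 value per symbol, which annotation was used and which genome build it followed were not given in the sources used here. Values ranged from 2.34 to 13.1. The 9 columns did not share 1 distribution. The median was 4.79 to 4.85 on 8 arrays and 5.05 on E16.5 replicate 2. The median of 1469 olfactory and vomeronasal receptor genes, used as a proxy for the low end of the signal because these genes serve smell and pheromone sensing, was 3.16 to 3.29 on 8 arrays and 3.66 on E16.5 replicate 2. Of the entries, 5702 (18.4%) had the same value on 3 or more arrays and 62 were identical to another entry on all 9 arrays. No detection calls were used here, so a gene near the low end of the scale may be below background, and fold changes of dim genes understate the change. The number of arrays limits the precision.

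Symbols were set against a mouse reference gene table of assembly GRCm38.p6, used for names alone. In it 26677 symbols were current, 1046 were older symbols and 3192 had no match and kept their deposited name. A further check found 13 entries whose names had been turned into dates, and none of these is named. No coordinates are given, because no build was stated.

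The design, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. limma 3.58.1 in R 4.3.3 was fitted to the deposited log2 values of all 9 arrays with stage as the only term (lmFit and eBayes, 6 residual degrees of freedom, prior degrees of freedom 4.59, prior SD 0.129). The planned choice of the brightest transcript cluster per gene was not needed, since the table already had 1 entry per symbol. The contrasts were E15.5 minus E14.5 (the first day), E16.5 minus E15.5 (the second day), E16.5 minus E14.5 (both days), and the second-day minus the first-day change. A moderated F-test covered any change over the 3 stages. P-values were two-sided and adjusted by the Benjamini-Hochberg method over 30915 genes in each contrast, with an adjusted p threshold of 0.05. All adjusted p-values of single genes below come from this limma fit. Values are given as log2 change ± standard error (SE) with 3 arrays per stage.

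Gene lists numbered 29 and had 722 listed members, of which 713 were matched, 5 of them under an older or newer symbol, while 7 were not in the table and 2 duplicated another member. They covered thermogenesis and brown identity, general adipocyte differentiation, adipose progenitors and mesenchyme, glycogen synthesis, glycogen breakdown, glucose uptake and glycolysis, the autophagy core machinery, the lysosome, lipid droplet proteins, fatty acid and triglyceride synthesis, mitochondrial fatty acid oxidation, the TCA cycle, oxidative phosphorylation, the circadian clock, the cell cycle, the extracellular matrix, Wnt, BMP and hedgehog signalling, imprinted growth genes, and white and beige adipocyte markers. Hormone receptors and thyroid hormone metabolism formed another. Lists for other cell types covered skeletal muscle, cartilage and bone, endothelium, mural and smooth muscle cells, erythroid cells, macrophages and other leukocytes, neurons and Schwann cells, epidermis, and liver as a tissue control. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 29 lists in each contrast. The test was repeated with a correlation estimated for each list. Members were also counted after adjustment over the list alone.

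Named genes followed a rule. It took, for each stage comparison, the 8 genes with the largest rise and the 8 with the largest fall among those that passed the threshold and whose 3 values at 1 stage all lay above the 3 at the other, leaving out gene models without a function-bearing name. Chance gives such separated groups for 10% of genes. The rule added up to 4 members of each list with the smallest p, and a fixed panel of brown fat, glycogen, autophagy, muscle and proliferation genes. Genes outside the rule are said to have been chosen after their values were seen. Some members that the rule took are not reported here.

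Each step was tested on simulated data in which 200 of 30915 genes were changed per comparison, split between log2 changes of 0.5, 1 and 2. For E15.5 against E14.5 the limma step recovered 37.3%, 91.0% and 100% of them at these sizes, for E16.5 against E15.5 it recovered 43.3%, 82.1% and 98.5%, and for E16.5 against E14.5 it recovered 38.8%, 88.1% and 100%. For the second-day minus the first-day change it recovered 0%, 31.3% and 89.4%, so in this setting that contrast missed small differences. The data gave 6275, 6076, 12171 and 1610 calls in these contrasts, far more than the 200 changed genes. More calls loosen the adjusted threshold, so the recovery shares hold for the simulated setting and may be higher in the data. The share of false calls was 5% for the first day, 6.88% for the second, 3.82% for both days and 6.98% for the difference. The F-test recovered 37.3%, 89.6% and 100% with 4.43% false calls.

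Alternatives were a second quantile normalization, centring each array on its median, leaving out genes below the median brightness, eBayes with an intensity trend or a robust prior, array weights, the replicate number as a block, each array left out in turn, fits to 6 arrays alone, and a minimum change of 2-fold. The mean of 4 Y-linked genes as a covariate, and quantile normalization without E16.5 replicate 2, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.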

Results

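Each of the 3 stages, E14.5, E15.5 and E16.5, was represented by 3 arrays, each from a separate pool of BAT from 3 embryos, and 30915 genes were tested. Arrays of 1 stage resembled each other more than arrays of different stages. Across genes, Pearson's r was at least 0.9978 within E14.5, at least 0.9975 within E15.5 and 0.992 to 0.997 within E16.5. Between stages it was 0.982 to 0.985 for E14.5 and E15.5, 0.982 to 0.989 for E15.5 and E16.5, and 0.952 to 0.962 for E14.5 and E16.5. These correlations are across genes, which are not independent replicates. The first principal component held 75.2% of the variance and ordered the arrays by stage, and the second held 11.3% and set E16.5 replicate 2 apart from the other arrays of its stage. The fit called 10849 genes changed over the 3 stages by the F-test.

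**Figure D1:**
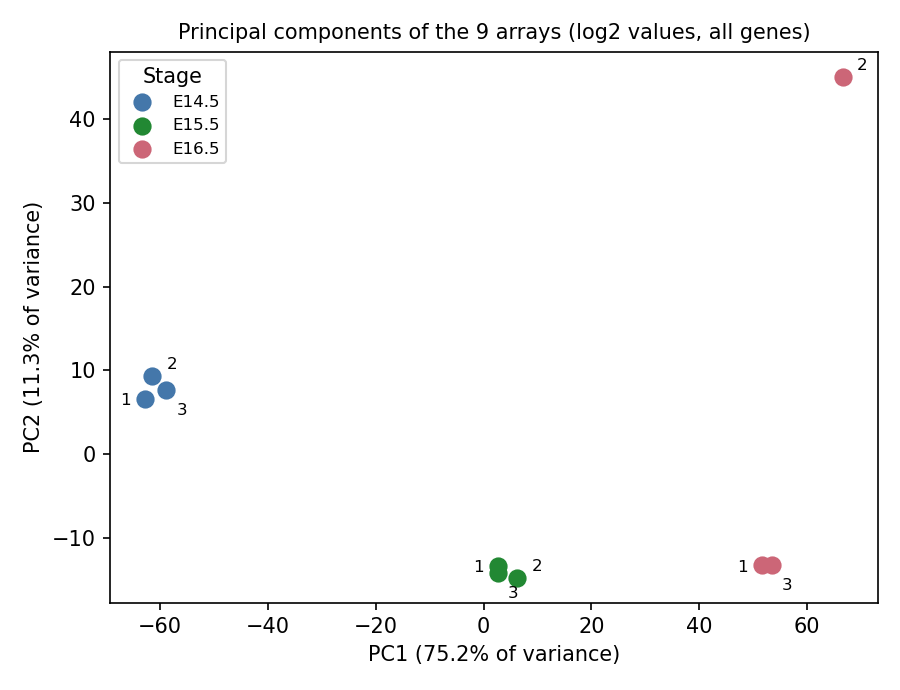
Scores of the 9 arrays on the first (x axis, 75.2% of the variance) and second principal component (y axis, 11.3%) of the log2 values, with 1 point per array, coloured by stage and numbered by replicate. The stages lie in order along the x axis, and E16.5 replicate 2 lies away from the other E16.5 arrays along the y axis.

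The deposited scale moved the median gene by 0.14 in log2 from E14.5 to E16.5 and by 0.10 from E15.5 to E16.5, against 0.0068 and -0.00091 after quantile normalization. Relative medians of gene lists below are therefore those less the median of all genes in the same comparison, while other medians are named as deposited and the changes of single genes are as deposited. Among genes at or above the median brightness the deposited moves were 5e-06 and 0.024, so the shift lay mostly in dimmer genes. For lists of brighter genes, subtracting the median of all genes may therefore lower the list median too far.

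The first comparison, E15.5 against E14.5, asks how embryonic BAT changes over 1 day of gestation. Genes of fat storage and of mitochondrial respiration rose, and genes of skeletal muscle, the extracellular matrix and mesenchymal progenitors fell. The largest rise among genes with function-bearing names was that of Cox7a1, a subunit of cytochrome c oxidase, at 35.1-fold (log2 change 5.13 ± 0.10, n = 3 arrays per stage, limma adjusted p = 7.20e-10). Cidec, which promotes lipid droplet growth, rose 34.6-fold (log2 change 5.11 ± 0.08), and Plin1, the perilipin that guards lipid droplets against lipolysis, rose 20.6-fold (log2 change 4.36 ± 0.09). The largest fall was that of Corin, a serine protease that processes natriuretic peptides, with a log2 change of -3.27 ± 0.12 (limma adjusted p = 5.37e-08).

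The other genes with the largest rises were the amino acid transporter Slc36a2 (log2 change 4.50), the mitochondrial protein gene Chchd10 (4.18), Mrap, an accessory protein of the ACTH receptor (4.14), the FGF21 co-receptor Klb (4.09) and the perilipin Plin4 (4.01). The other genes with the largest falls were the glycosyltransferase B4galnt4 (-2.97), the secreted Wnt antagonist Frzb (-2.66), the retinoic acid-binding protein Crabp2 (-2.65), the hyaluronan-degrading Cemip (-2.61), Rimklb (-2.48), the netrin receptor Dcc (-2.48) and the myosin-binding protein Mybph (-2.42). In all, 6275 genes changed, of which 2803 rose and 3472 fell, and 503 rose and 721 fell at least 2-fold. The counts were 4413 and 4640 without E16.5 replicate 2, and 4546 and 4723 in a fit to the 6 arrays of these stages alone.

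Thermogenic genes rose on the first day. In the thermogenesis and brown identity list, of 29 measured members, 21 rose and 3 fell (21 and 3 adjusted over the list alone), with a relative median of 0.84 (camera adjusted p = 1.46e-12, 0.0433 with an estimated correlation). Cidea rose by 3.98 ± 0.11, the coactivator Ppargc1a, which drives mitochondrial biogenesis, by 2.43 ± 0.09, and the potassium channel Kcnk3 by 3.09 ± 0.12. Ucp1, the uncoupling protein that makes brown fat produce heat, rose by 1.06 ± 0.12, and Prdm16, a determinant of brown fate, by 0.88 ± 0.10. The early brown fat regulator Ebf2 had 0.27 ± 0.08, a call that ended without E14.5 replicate 2 (0.23), E14.5 replicate 3 (0.27) or E15.5 replicate 1, 2 or 3 (0.28, 0.30 and 0.24). In the adipocyte differentiation list, of 29 measured members, 27 rose and 0 fell (27 and 0 adjusted over the list alone). Its relative median was 1.37 (camera adjusted p = 6.50e-30). Among them Adig rose by 3.33, Acvr1c by 3.93, Retn by 3.07 and the glycerol channel Aqp7 by 3.31. The adipogenic regulators Pparg and Cebpa rose by 0.38 ± 0.08 and 1.31 ± 0.11, Adipoq (adiponectin) by 2.46 ± 0.11 and the fatty acid carrier Fabp4 by 1.20 ± 0.09. In the lipid droplet list, of 24 measured members, 16 rose and 1 fell (16 and 1 adjusted over the list alone). The list had a relative median of 0.81 (camera adjusted p = 3.83e-14), led by Cidec, Plin1, the lipase Pnpla2 (3.51) and Cidea, while Plin2 had a value of 0.20 ± 0.10 that did not pass.

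Mitochondrial lists rose with few exceptions. In fatty acid oxidation, of 21 measured members, 19 rose and 0 fell (19 and 0 adjusted over the list alone). Relative to all genes its median was 1.07 (camera adjusted p = 1.78e-21), with Acadl at 1.72, Acsl1 at 2.17, Eci1 at 1.60 and Acadm at 1.78. In the TCA cycle, of 23 measured members, 22 rose and 0 fell (22 and 0 adjusted over the list alone). The median of the list, relative to all genes, was 1.0 (camera adjusted p = 1.15e-25), led by pyruvate carboxylase Pcx (2.18), Idh3a (1.67), Dld (1.28) and Pdhb (1.44). For oxidative phosphorylation the count was 42 higher and 0 lower of 48 (44 and 0 adjusted over the list alone; relative median 0.74, camera adjusted p = 3.56e-29), led by Uqcrfs1 (1.66), Cyc1 (1.14), Ndufs1 (1.04) and Ndufb9 (1.16). Over the same day the skeletal muscle list fell, with a relative median of -1.13.

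Enzymes of carbohydrate and lipid storage moved in both directions. In the glycogen synthesis list, of 14 measured members, 8 rose and 3 fell (8 and 4 adjusted over the list alone), with a relative median of 0.29 (camera adjusted p = 0.0128, adjusted p = 0.47 with an estimated correlation). The branching enzyme Gbe1 rose by 1.20 ± 0.10, the glycogen-targeting phosphatase subunits Ppp1r3d and Ppp1r3c by 1.33 ± 0.12 and 1.06 ± 0.10, and the primer protein glycogenin (Gyg) by 0.85 ± 0.09. The phosphatase subunit Ppp1r3b had 0.37 ± 0.11, glycogen synthase Gys1 0.72 ± 0.07 (adjusted p = 3.78e-05), the liver synthase Gys2 0.14 ± 0.10 (adjusted p = 0.447) and Ugp2, which makes UDP-glucose, -0.27 ± 0.09 (adjusted p = 0.0512). In the glycogen breakdown list, of 13 measured members, 3 rose and 3 fell (3 and 4 adjusted over the list alone). A relative median of -0.14 was found (camera adjusted p = 0.504), and 1 fell without E14.5 replicate 1, E15.5 replicate 2 or E15.5 replicate 3. The phosphorylase Pygl rose by 0.67 ± 0.09 and the muscle phosphorylase Pygm fell (log2 change -0.77 ± 0.11), while the skeletal muscle list fell on the same day. The lysosomal glucosidase Gaa had -0.32 ± 0.08, Epm2a (laforin) 0.37 ± 0.10, Pygb -0.02 ± 0.08 (adjusted p = 0.917) and the glycogen-binding Stbd1 -0.27 ± 0.10 (adjusted p = 0.0938). Leaving out E14.5 replicate 2 or 3 or E15.5 replicate 2 or 3 ended the calls of Ppp1r3b (0.29, 0.39, 0.37 and 0.30) and Epm2a (0.31, 0.36, 0.37 and 0.37), leaving out E15.5 replicate 1 that of Epm2a (0.38), and leaving out E14.5 replicate 1 or E15.5 replicate 2 or 3 that of Gaa (-0.29, -0.30 and -0.30). In glucose uptake and glycolysis, of 31 measured members, 12 rose and 6 fell (14 and 9 adjusted over the list alone) (relative median -0.0045 while the mean was 0.25 as deposited, camera adjusted p = 0.0925), and without E16.5 replicate 2 the number that fell was 10. The pyruvate dehydrogenase kinases Pdk4 and Pdk1 rose by 1.85 and 1.33, Pfkfb1 by 1.30 and Pgam1 by 1.32.

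In fatty acid and triglyceride synthesis, of 25 measured members, 11 rose and 7 fell (11 and 7 adjusted over the list alone). Its members had a relative median of 0.14 (camera adjusted p = 0.0216, adjusted p = 0.229 with an estimated correlation). The camera call also ended without E16.5 replicate 2 (adjusted p = 0.0683), with quantile normalization (0.0551) and with median centring (0.119). The carbohydrate-sensing factor Mlxipl rose by 2.66 ± 0.12, the triglyceride synthases Dgat2 and Dgat1 by 1.55 ± 0.08 and 1.33 ± 0.08, and Lpin1 by 2.0 ± 0.11, whereas the desaturase Scd1 fell (log2 change -1.42 ± 0.12). In the autophagy list, of 36 measured members, 7 rose and 2 fell (10 and 4 adjusted over the list alone). The relative median of this list was 0.03 (camera adjusted p = 0.105), and 12 rose and 5 fell without E16.5 replicate 2. The mitophagy receptor Bnip3 rose by 1.15 ± 0.10, Atg4d by 1.17 ± 0.12, Atg10 by 0.72 ± 0.08 and the receptor Optn by 0.69 ± 0.12. Ulk1 had 0.05 ± 0.08 (adjusted p = 0.801), Map1lc3b 0.24 ± 0.08 (adjusted p = 0.0538) and Sqstm1 -0.09 ± 0.08 (adjusted p = 0.573). In the lysosome list, of 28 measured members, 5 rose and 2 fell (5 and 3 adjusted over the list alone). Its relative median was -0.03 (camera adjusted p = 0.833), and 8 fell without E16.5 replicate 2. Tfeb, a master regulator of lysosomal genes, rose by 0.49, and Gusb changed by -0.40. In the circadian clock list, of 19 measured members, 10 rose and 1 fell (11 and 1 adjusted over the list alone). The list had a relative median of 0.30 (camera adjusted p = 8.00e-04, adjusted p = 0.231 with an estimated correlation), with Per3 at 1.05, Npas2 at 1.03, Dbp at 0.73, Hlf at 0.96 and Nr1d1 at 0.11 (adjusted p = 0.581), and 6 rose without E14.5 replicate 1 or without E15.5 replicate 2. The time of day of sampling was not given in the sources used here.

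Cell cycle genes rose modestly on the first day by the preset test. Of 40 measured, 9 rose and 2 fell (9 and 3 adjusted over the list alone). Relative to all genes their median was 0.12 (camera adjusted p = 0.00665, adjusted p = 0.683 with an estimated correlation), and 18 rose and 4 fell without E16.5 replicate 2. The replication regulator E2f2 rose by 0.95 ± 0.10, the ribonucleotide reductase subunit Rrm2 by 0.75 ± 0.09 and Birc5 by 0.49 ± 0.08, cyclin Ccnd1 fell (log2 change -0.60 ± 0.08), and the proliferation marker Mki67 had 0.03 ± 0.08 (adjusted p = 0.91). In the hormone receptor list, of 26 measured members, 9 rose and 3 fell (9 and 3 adjusted over the list alone). The median of the list, relative to all genes, was 0.02 (camera adjusted p = 0.203). The retinoid receptor Rxrg rose by 1.30, while Fgfr4 and Igf1r fell (log2 changes -1.58 and -0.91). Among white and beige adipocyte markers, of 15 measured members, 4 rose and 4 fell (4 and 4 adjusted over the list alone). A relative median of -0.05 was found (camera adjusted p = 0.853, downward, as was the median, while the mean lay above 0 as deposited), with leptin (Lep) at 1.94 and Tmem26 at -1.54.

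Structural and signalling genes of the mesenchyme fell on the first day. In the extracellular matrix list, of 32 measured members, 1 rose and 22 fell (1 and 25 adjusted over the list alone). Its members had a relative median of -0.74 (camera adjusted p = 8.53e-18), with thrombospondin Thbs1 at -1.55 ± 0.08, Tnc at -1.47 ± 0.11, Fbn2 at -1.32 ± 0.10, Vcan at -1.0 ± 0.08 and the collagen gene Col1a1 at -0.71 ± 0.08. In the progenitor list, of 27 measured members, 2 rose and 13 fell (2 and 18 adjusted over the list alone). The relative median of this list was -0.39 (camera adjusted p = 6.07e-08), with Cd24a at -1.54, Sox9 at -1.63, Osr1 at -1.51 and the receptor Pdgfra, which marks adipose precursors, at -1.02 ± 0.09. The preadipocyte factor Dlk1 had -0.20 ± 0.11 (adjusted p = 0.266). In Wnt, BMP and hedgehog signalling, of 32 measured members, 3 rose and 21 fell (3 and 22 adjusted over the list alone). Its relative median was -0.68 (camera adjusted p = 1.46e-12), with Sfrp2 at -1.45, Dkk2 at -1.97, Gdf10 at -1.45 and Gli2 at -1.20. Among imprinted growth genes, of 19 measured members, 2 rose and 14 fell (2 and 14 adjusted over the list alone). The list had a relative median of -0.52 (camera adjusted p = 1.99e-08), with Peg10 at -0.93, Mirg at -1.52, the growth inhibitor Cdkn1c at -1.01 and, in the opposite direction, Nnat at 0.99. The muscle list fell beside these lists. All of these camera calls of falling lists held with an estimated correlation, but only just. Their adjusted p was then 0.0438 for the matrix, 0.0433 for progenitors, 0.0433 for signalling and 0.0430 for imprinted genes.

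Markers of other cell types moved apart on the first day. In the skeletal muscle list, of 32 measured members, 0 rose and 31 fell (0 and 32 adjusted over the list alone), with a relative median of -1.13 (camera adjusted p = 1.37e-26, 0.0433 with an estimated correlation). The myogenic regulators Myog and Myod1 fell (log2 changes -1.80 ± 0.11 and -1.76 ± 0.12), as did Tmem8c, the older name of the fusion protein Mymk (-1.61), and Chrnd (-1.39). In the neuron and Schwann cell list, of 20 measured members, 0 rose and 9 fell (0 and 9 adjusted over the list alone). Relative to all genes its median was -0.34 (camera adjusted p = 1.16e-04, adjusted p = 0.191 with an estimated correlation), with Erbb3 at -1.64, Ngfr at -1.25 and Nefl at -1.49. In the leukocyte list, of 24 measured members, 1 rose and 11 fell (4 and 12 adjusted over the list alone). The median of the list, relative to all genes, was -0.32 (camera adjusted p = 0.00262, adjusted p = 0.481 with an estimated correlation), and 7 fell without E14.5 replicate 1, E15.5 replicate 2 or E15.5 replicate 3, while 3 rose without E16.5 replicate 1 or 2. Its macrophage genes Itgam, Mrc1, Csf1r and Adgre1 fell (log2 changes -0.59, -0.62, -0.61 and -0.62). Counts for endothelium were 2 higher and 4 lower of 22 (2 and 4 adjusted over the list alone; 2 lower without any 1 of the E14.5 arrays, E15.5 replicate 2 or E15.5 replicate 3), with Gpihbp1, which carries lipoprotein lipase across capillaries, at 0.76 and Vwf at -1.0. For mural cells they were 3 and 5 of 12 (4 and 5 adjusted over the list alone), with the pericyte marker Rgs5 at 1.59 and Acta2 at -0.71. Erythroid genes gave 1 and 5 of 18 (1 and 5 adjusted over the list alone), with the transferrin receptor Tfrc at 2.17 and embryonic globins Hbb-y and Hba-x at -1.19 and -0.65. Cartilage and bone gave 0 and 4 of 24 (0 and 4 adjusted over the list alone), where 8 fell without E16.5 replicate 2, 1 without E14.5 replicate 1 or E15.5 replicate 1, and 2 without E14.5 replicate 3, E15.5 replicate 2 or E15.5 replicate 3. Epidermis gave 1 and 0 of 16 (1 and 0 adjusted over the list alone), and liver 1 and 0 of 14 (0 and 0 adjusted over the list alone). The camera adjusted p of these lists was 0.327 for endothelium, 0.501 for mural cells, 0.143 for erythroid cells, 0.205 for cartilage and bone, 0.503 for epidermis and 0.143 for liver. Cartilage and bone had a median above 0 as deposited, while its mean lay below 0 and camera placed it downward.

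The second comparison, E16.5 against E15.5, asks the same of the following day. Genes of lipid synthesis rose and genes of the extracellular matrix fell. By the preset test genes of heat production also rose and genes of cell division fell (adjusted p = 0.0692 and 0.0692 with an estimated correlation). Ucp1 rose 13-fold (log2 change 3.70 ± 0.12, n = 3 arrays per stage, limma adjusted p = 9.23e-08), and Cox8b, a cytochrome c oxidase subunit typical of brown fat, rose 11.8-fold (log2 change 3.56 ± 0.13). Dio2, the deiodinase that activates thyroid hormone, rose by 3.31 ± 0.17, and Scd1, the desaturase that makes monounsaturated fatty acids, by 2.91 ± 0.12. The embryonic globin Hbb-y had the largest fall among genes with function-bearing names (log2 change -2.67 ± 0.17, limma adjusted p = 4.13e-06).

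Other genes with the largest rises on the second day were the membrane protein gene Tmem45b (4.34), Cpn2, a subunit of carboxypeptidase N (3.23), the mitochondrial carrier Slc25a35 (2.81) and Pck1, the enzyme of glyceroneogenesis (2.63). Other genes with the largest falls were the small nucleolar RNA gene AF357425 (-2.09), the endopeptidase Phex (-1.97), the hyaluronan synthase Has2 (-1.87), the mitochondrial tRNA gene mt-Tn (-1.86), the transcription factor Sox9 (-1.81), the small nucleolar RNA host Gas5 (-1.81) and Tmem178 (-1.74). In all, 6076 genes changed, of which 3461 rose and 2615 fell, and 438 rose and 216 fell at least 2-fold. The share that rose was 57.0% as deposited and 46.2% after centring each array on its median (3466 rose and 4039 fell). Without E16.5 replicate 2 the counts were 3581 and 4196.

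By the preset test the thermogenic and adipocyte lists rose again (adjusted p = 0.0692 and 0.0776 with an estimated correlation). In thermogenesis and brown identity, of 29 measured members, 19 rose and 2 fell (19 and 2 adjusted over the list alone). A relative median of 0.68 was found (camera adjusted p = 7.04e-10, adjusted p = 0.0692 with an estimated correlation), and the counts were 19 and 2 without E16.5 replicate 2. Cidea rose by 2.40 ± 0.11 and Ppargc1a by 0.78 ± 0.09, while Prdm16 had 0.18 ± 0.10 (adjusted p = 0.281) and Ebf2 0.04 ± 0.08 (adjusted p = 0.736). In adipocyte differentiation, of 29 measured members, 21 rose and 0 fell (22 and 0 adjusted over the list alone). Its members had a relative median of 0.35 (camera adjusted p = 7.28e-10, adjusted p = 0.0776 with an estimated correlation), and the counts were 20 and 2 without E16.5 replicate 2. Adig rose by 2.47, the complement factor Cfd by 2.40 and Retn by 1.58. In the lipid droplet list, of 24 measured members, 15 rose and 0 fell (16 and 0 adjusted over the list alone). The relative median of this list was 0.44 (camera adjusted p = 7.42e-09), led by Cidea, Plin5 (2.18), Mgll (1.30) and Cideb (1.42), while Plin1 rose by 1.11 ± 0.09 and Plin2 had 0.20 ± 0.10 (adjusted p = 0.203). In fatty acid and triglyceride synthesis, of 25 measured members, 16 rose and 1 fell (19 and 1 adjusted over the list alone). Its relative median was 0.51 (camera adjusted p = 5.81e-10), with Scd1, Acacb (2.61), Dgat1 (1.11) and Agpat3 (1.03). The adipocyte regulators Pparg, Cebpa, Adipoq and Fabp4 had 0.31 ± 0.08, 0.44 ± 0.11, 0.38 ± 0.11 and 0.34 ± 0.09, calls that did not hold in every fit. That of Pparg ended without E15.5 replicate 1, 2 or 3 (0.32, 0.30 and 0.30) and with quantile normalization (0.15) or median centring (0.24). That of Adipoq ended without E14.5 replicate 1 (0.38), any 1 of the E15.5 arrays (0.36, 0.42 and 0.37), E16.5 replicate 1 (0.40) or E16.5 replicate 2 (0.31) and with median centring (0.31). The call of Cebpa ended without E15.5 replicate 1 or 3 (0.44 in both), and that of Fabp4 without E15.5 replicate 2 or 3 (0.30 and 0.33) or E16.5 replicate 1 or 3 (0.32 in both) and with median centring (0.27).

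The mitochondrial lists rose again. In fatty acid oxidation, of 21 measured members, 21 rose and 0 fell (21 and 0 adjusted over the list alone). The list had a relative median of 0.66 (camera adjusted p = 1.23e-15), led by the carnitine carrier Slc25a20 (1.87), Eci1 (1.17), Etfdh (1.12) and Decr1 (0.90). In the TCA cycle, of 23 measured members, 22 rose and 0 fell (22 and 0 adjusted over the list alone). Relative to all genes its median was 0.41 (camera adjusted p = 1.58e-12), led by Sucla2 (1.09) and Suclg1 (0.90). For oxidative phosphorylation, of 48 measured members, 40 rose and 1 fell (43 and 1 adjusted over the list alone). The median of the list, relative to all genes, was 0.41 (camera adjusted p = 5.51e-16), led by Ndufa1 (1.17), Uqcrfs1 (1.02), Atp5e (0.86) and Ndufs1 (0.77). Without E16.5 replicate 2 the counts were 20 and 0 for fatty acid oxidation, 22 and 0 for the TCA cycle and 42 and 1 for oxidative phosphorylation. Skeletal muscle genes had a relative median of -0.31 on this day.

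Glycogen synthesis genes rose by the preset test. Of 14 measured, 9 rose and 0 fell (9 and 0 adjusted over the list alone). A relative median of 0.36 was found (camera adjusted p = 4.55e-05, adjusted p = 0.182 with an estimated correlation), and the counts were 9 and 0 without E16.5 replicate 2. Ppp1r3c rose by 1.82 ± 0.10, Gbe1 by 1.72 ± 0.10, Ppp1r3b by 1.46 ± 0.11, Gyg by 0.66 ± 0.09 and Ugp2 by 0.49 ± 0.09, whereas Gys1 had 0.46 ± 0.07 (adjusted p = 0.00118) and Gys2 0.46 ± 0.10 (adjusted p = 0.00616), the latter with means below the 95th percentile of the receptor genes at every stage. In glycogen breakdown, of 13 measured members, 4 rose and 0 fell (4 and 1 adjusted over the list alone). Its members had a relative median of 0.06 (camera adjusted p = 0.14), and those that rose included Epm2a (1.21 ± 0.10), Pygl (0.58 ± 0.09) and Stbd1 (0.61 ± 0.10). Gaa had 0.02 ± 0.08 (adjusted p = 0.885) and Pygb -0.00 ± 0.08 (adjusted p = 0.996). In glucose uptake and glycolysis, of 31 measured members, 12 rose and 1 fell (15 and 1 adjusted over the list alone). The relative median of this list was 0.13 (camera adjusted p = 0.0014, adjusted p = 0.182 with an estimated correlation), led by Pdk4 (1.64), the insulin-responsive transporter Slc2a4 (1.17), Pfkfb1 (1.12) and Pdk1 (0.87).

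In the autophagy list, of 36 measured members, 15 rose and 0 fell (18 and 0 adjusted over the list alone). Its relative median was 0.18 (camera adjusted p = 8.12e-05, adjusted p = 0.499 with an estimated correlation), and the counts were 17 and 1 without E16.5 replicate 2. Optn rose by 1.38 ± 0.12, Atg10 by 0.89 ± 0.08, Bnip3 by 0.93 ± 0.10 and Atg4d by 0.89 ± 0.12. Ulk1 had 0.04 ± 0.08 (adjusted p = 0.72), Map1lc3b 0.40 ± 0.08 (adjusted p = 0.00382) and Sqstm1 -0.02 ± 0.08 (adjusted p = 0.859). In the lysosome list, of 28 measured members, 12 rose and 3 fell (14 and 3 adjusted over the list alone). The list had a relative median of 0.15 (camera adjusted p = 0.0453, adjusted p = 0.648 with an estimated correlation), with the cathepsins Ctsd and Ctsb at 0.78 and 0.48, Atp6v1h at 0.58 and Gusb at -0.60. The lysosome call of camera also ended without E15.5 replicate 1 (adjusted p = 0.0546), E15.5 replicate 3 (0.0543), E16.5 replicate 1 (0.108) or E16.5 replicate 3 (0.0745) and with median centring (0.0608), and 7 members rose and 1 fell without any 1 of the E15.5 arrays. The number that fell was 1 without E16.5 replicate 3 and 5 without E16.5 replicate 2. In the circadian clock list, of 19 measured members, 9 rose and 0 fell (14 and 1 adjusted over the list alone). Relative to all genes its median was 0.25 (camera adjusted p = 4.44e-04, adjusted p = 0.201 with an estimated correlation), with Bhlhe40 at 1.01, Arntl at 0.68, Dbp at 0.68 and Nr1d1 at 0.56 ± 0.09 (adjusted p = 0.0016). In the hormone receptor list, of 26 measured members, 9 rose and 3 fell (10 and 3 adjusted over the list alone). The median of the list, relative to all genes, was 0.12 (camera adjusted p = 0.0574; 5 fell without E16.5 replicate 2), led by Dio2, the adrenergic receptor Adra1a (1.23), the thyroid hormone receptor Thrb (1.26) and Klb (0.99). Among white and beige adipocyte markers, of 15 measured members, 5 rose and 3 fell (5 and 4 adjusted over the list alone). A relative median of -0.02 was found (camera adjusted p = 0.587, downward, while the median lay above 0 and the mean just below it as deposited; 3 rose without E15.5 replicate 2 and 2 without E15.5 replicate 3), with Tmem26 at -1.67, Cited1 at -0.85 and Nnmt at 0.74.

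Cell cycle genes fell on the second day by the preset test. Of 40 measured, 0 rose and 38 fell (0 and 38 adjusted over the list alone). They had a relative median of -0.77 (camera adjusted p = 2.05e-33, adjusted p = 0.0692 with an estimated correlation), and the counts were 0 and 38 without E16.5 replicate 2. The replication licensing genes Mcm3 and Mcm2 fell (log2 changes -0.99 ± 0.08 and -0.95 ± 0.08), as did Cdc6 (-1.16 ± 0.10), the kinetochore motor Cenpe (-0.93 ± 0.08) and Mki67 (-0.68 ± 0.08). In the extracellular matrix list, of 32 measured members, 0 rose and 27 fell (0 and 28 adjusted over the list alone). The relative median of this list was -0.67 (camera adjusted p = 1.26e-22), with Fbn2 at -1.42, the protease Mmp2 at -0.98, Vcan at -0.90, Fmod at -1.36 and Col1a1 at -0.46 ± 0.08. In the progenitor list, of 27 measured members, 1 rose and 11 fell (1 and 11 adjusted over the list alone). Its relative median was -0.26 (camera adjusted p = 3.95e-07, adjusted p = 0.0692 with an estimated correlation), with Pdgfra at -0.94 ± 0.09, Gata6 at -0.99, Prrx1 at -0.68 and Dlk1 at -0.61 ± 0.11 (adjusted p = 0.00223). In Wnt, BMP and hedgehog signalling, of 32 measured members, 2 rose and 10 fell (2 and 12 adjusted over the list alone). The list had a relative median of -0.24 (camera adjusted p = 1.01e-06, adjusted p = 0.123 with an estimated correlation), with Sfrp2 at -1.24, Gli3 at -1.20, Sfrp1 at -1.19 and Bmp7 at -1.04. Among imprinted growth genes, of 19 measured members, 1 rose and 13 fell (1 and 14 adjusted over the list alone). Relative to all genes its median was -0.74 (camera adjusted p = 1.32e-11), with the amino acid transporter Slc38a4 at -1.13, Peg3 at -0.75, Peg10 at -0.74 and Plagl1 at -0.68. Without E16.5 replicate 2 the counts were 0 and 27 for the matrix, 0 and 12 for progenitors, 2 and 12 for signalling and 1 and 14 for imprinted genes.

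Of the other cell types, the skeletal muscle list fell by the preset test on the second day. Of 32 measured, 1 rose and 14 fell (2 and 14 adjusted over the list alone). The median of the list, relative to all genes, was -0.31 (camera adjusted p = 1.40e-05, adjusted p = 0.34 with an estimated correlation), and the counts were 4 and 13 without E16.5 replicate 2, the array on which muscle genes lay at a median log2 deviation of -0.45 from genes of the same brightness. The number that fell was 8 without E15.5 replicate 1 or without E15.5 replicate 3. Myh7, Myog, the troponin Tnnt2 and Myod1 fell (log2 changes -0.84 ± 0.10, -0.88 ± 0.11, -0.96 ± 0.15 and -0.71 ± 0.12). In the erythroid list, of 18 measured members, 4 rose and 2 fell (4 and 2 adjusted over the list alone), with Hbb-y and Hba-x (-0.57) falling and Tfrc (0.60) and the adult globin Hbb-bs (0.89) rising, the last of which has a near-identical neighbour, Hbb-bt, so its value is uncertain. Endothelium gave 4 higher and 0 lower of 22 (5 and 0 adjusted over the list alone; 2 higher without E15.5 replicate 1 or 3), led by Gpihbp1 (0.75) and Cldn5 (0.62). Leukocytes gave 4 and 1 of 24 (4 and 2 adjusted over the list alone, 5 and 5 without E16.5 replicate 2), with S100a8 at 1.09, S100a9 at 0.70, though below the 95th percentile of the receptor genes at both stages, and the mast cell protease Mcpt4 at 1.34. Neurons and Schwann cells gave 2 and 2 of 20 (2 and 2 adjusted over the list alone). Mural cells gave 0 and 1 of 12 (0 and 1 adjusted over the list alone), and cartilage and bone 2 and 2 of 24 (2 and 2 adjusted over the list alone; 4 higher without E16.5 replicate 1 and 4 lower without E16.5 replicate 2), where Alpl fell and Sox5 rose (log2 changes -1.65 and 1.17). Epidermis gave 2 and 0 of 16 (2 and 0 adjusted over the list alone) and liver 1 and 1 of 14 (1 and 1 adjusted over the list alone). Camera adjusted p was 0.724 for erythroid cells, 0.065 for endothelium, 0.58 for leukocytes, 0.724 for neurons and Schwann cells, 0.601 for mural cells, 0.446 for cartilage and bone, 0.222 for epidermis and 0.724 for liver. The mural, the leukocyte and the neuron and Schwann cell lists had a median and mean above 0 as deposited while camera, which compares them with all genes, placed them downward, and cartilage and bone had a median above 0 with its mean and camera downward.

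**Figure D2:**
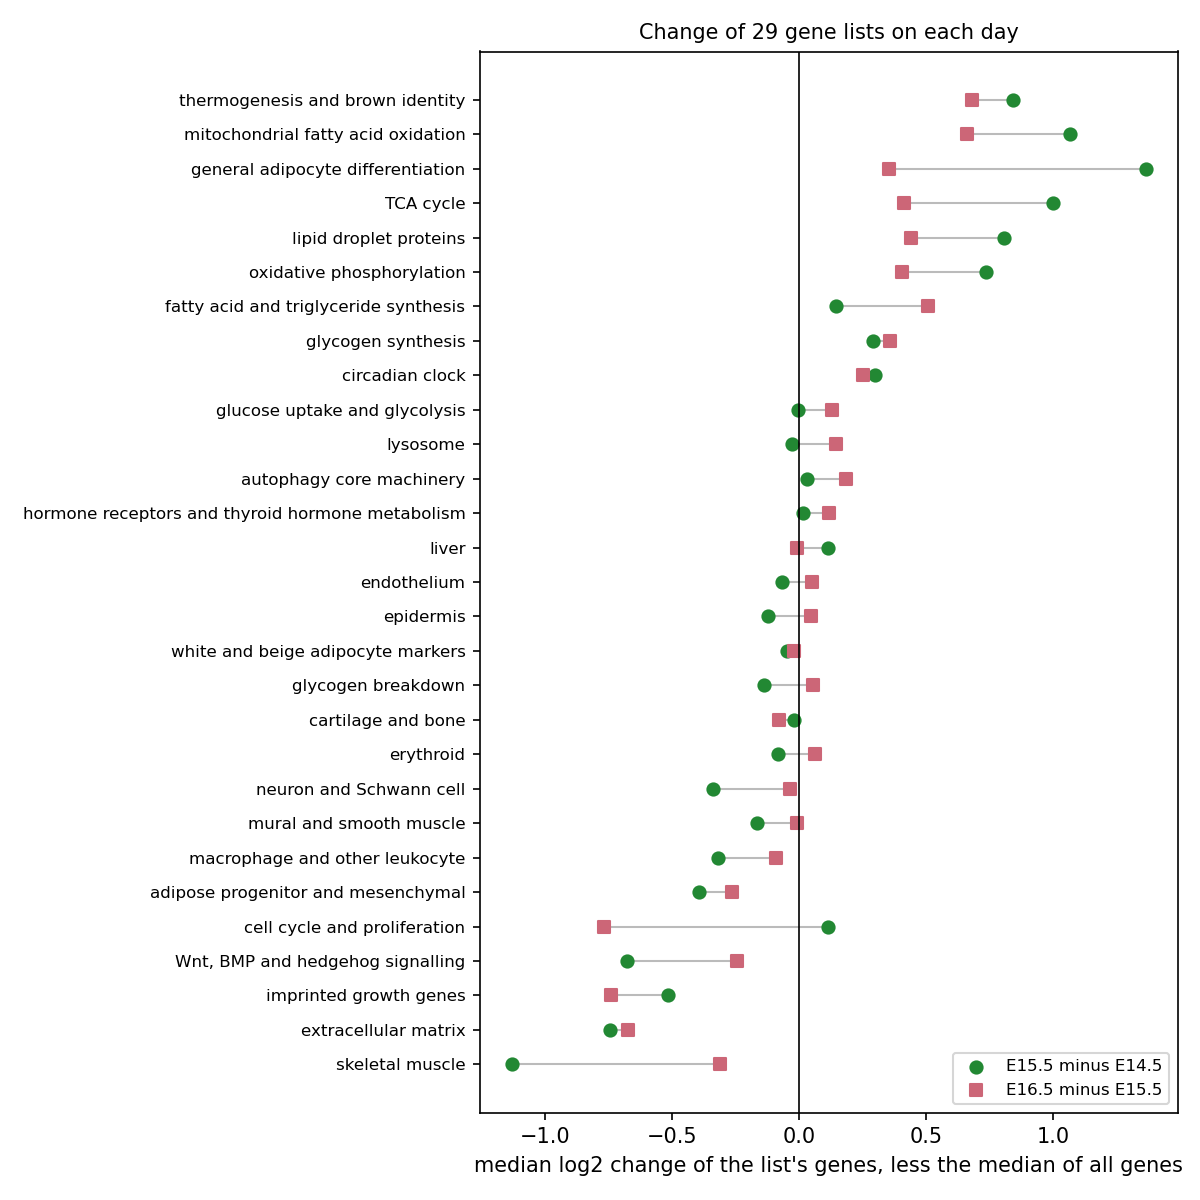
Median log2 change of the members of each of the 29 gene lists, less the median of all genes (x axis), on the first day (circles) and on the second day (squares), 1 line per list ordered by the change over both days. Adipocyte, lipid droplet and mitochondrial lists lie above 0 on both days, extracellular matrix and progenitor lists lie below 0 on both, and the cell cycle list lies at 0.12 on the first and -0.77 on the second day.

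The third comparison, E16.5 against E14.5, spans both days. Lipid storage and mitochondrial genes were higher and matrix and progenitor genes were lower at the end. By the preset test brown fat identity genes were also higher and signalling and muscle genes lower (adjusted p = 0.0592, 0.0501 and 0.0592 with an estimated correlation). Cox7a1 rose 119-fold (log2 change 6.90 ± 0.10, n = 3 arrays per stage, limma adjusted p = 2.12e-11), Cidea 83.2-fold (6.38 ± 0.11) and Ucp1 27.1-fold (4.76 ± 0.12), Ucp1 going from a mean log2 value of 4.46 ± 0.21 (SD) at E14.5 to 9.22 ± 0.19 at E16.5. Crabp2 and the secreted matrix protein Egfl6 fell (log2 changes -4.0 ± 0.11 and -3.80 ± 0.13). Further large rises were those of Cidec (6.21), Slc36a2 (6.03), Adig (5.81), Pck1 (5.80), Plin4 (5.61) and Plin1 (5.47), and further large falls those of Hbb-y (-3.86), AF357425 (-3.70), Clstn2 (-3.47), Corin (-3.45), Sox9 (-3.44) and Mybph (-3.34). In all, 12171 genes changed, of which 6795 rose and 5376 fell, and 1681 rose and 1550 fell at least 2-fold. Without E16.5 replicate 2 the counts were 6335 and 6720.

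Over both days, the panel gave Ppargc1a 3.21 ± 0.09, Prdm16 1.05 ± 0.10, Pparg 0.69 ± 0.08, Cebpa 1.76 ± 0.11, Adipoq 2.85 ± 0.11 and Fabp4 1.54 ± 0.09, all of which passed. Gbe1 rose by 2.92 ± 0.10 and Ppp1r3c by 2.89 ± 0.10, which is 7.59-fold and 7.4-fold, Ppp1r3b by 1.83 ± 0.11, Pygl by 1.25 ± 0.09, Epm2a by 1.59 ± 0.10 and Gyg by 1.51 ± 0.09. Gys1 had 1.19 ± 0.07 (adjusted p = 2.75e-07), Gys2 0.59 ± 0.10 (adjusted p = 4.71e-04), Ugp2 0.22 ± 0.09 (adjusted p = 0.0755) and Pygb -0.02 ± 0.08 (adjusted p = 0.804). Gaa, Stbd1, Ebf2 and Plin2 had -0.30 ± 0.08, 0.34 ± 0.10, 0.32 ± 0.08 and 0.41 ± 0.10, and these calls did not hold in every fit. Quantile normalization ended those of Ebf2 (0.15) and Plin2 (0.30), and median centring that of Plin2 (0.34). The call of Stbd1 ended without E14.5 replicate 1, 2 or 3 (0.31, 0.35 and 0.36) or E16.5 replicate 3 (0.32), that of Gaa without E14.5 replicate 1 (-0.27) and that of Ebf2 without E14.5 replicate 2 (0.27). Of the autophagy genes Ulk1 had 0.09 ± 0.08 (adjusted p = 0.348), Map1lc3b 0.63 ± 0.08 (adjusted p = 5.23e-05) and Sqstm1 -0.11 ± 0.08 (adjusted p = 0.264). Myog, Pdgfra, Col1a1 and Mki67 fell (log2 changes -2.68 ± 0.11, -1.96 ± 0.09, -1.17 ± 0.08 and -0.65 ± 0.08), Nr1d1 had 0.67 ± 0.09 (adjusted p = 1.73e-04) and Dlk1 had -0.81 ± 0.11 (adjusted p = 1.06e-04).

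**Figure D3:**
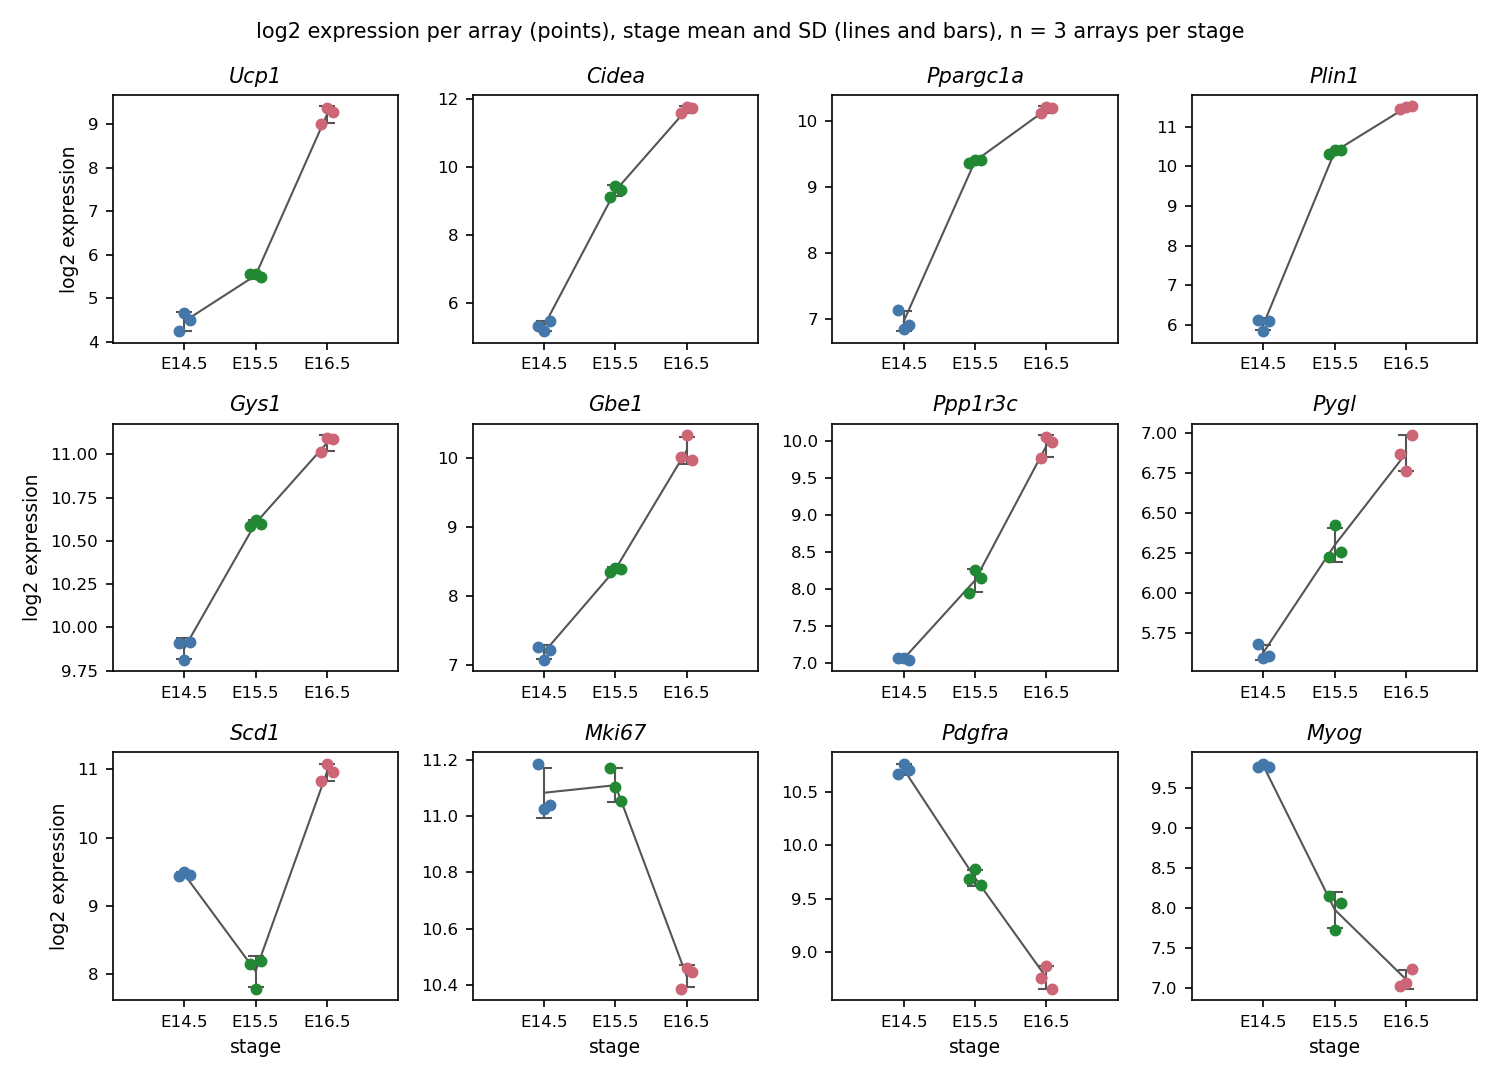
log2 expression (y axis) of 12 genes at E14.5, E15.5 and E16.5 (x axis), with 1 point per array, lines through the stage means and bars of 1 SD, n = 3 arrays per stage. Ucp1 has means of 4.46 ± 0.21, 5.52 ± 0.04 and 9.22 ± 0.19 (SD), and the y axes differ between genes.

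Gene lists over both days had the following counts. In thermogenesis and brown identity, of 29 measured members, 22 rose and 3 fell (24 and 3 adjusted over the list alone). A relative median of 1.97 was found (camera adjusted p = 6.78e-10, adjusted p = 0.0592 with an estimated correlation). In adipocyte differentiation, of 29 measured members, 27 rose and 0 fell (27 and 0 adjusted over the list alone). Its members had a relative median of 1.86 (camera adjusted p = 6.74e-18). In lipid droplet proteins, of 24 measured members, 20 rose and 2 fell (20 and 2 adjusted over the list alone). In fatty acid and triglyceride synthesis, of 25 measured members, 17 rose and 4 fell (17 and 4 adjusted over the list alone), and in fatty acid oxidation, of 21 measured members, 21 rose and 0 fell (21 and 0 adjusted over the list alone). These 3 lists had relative medians of 1.49, 0.95 and 1.93 and camera adjusted p-values of 3.92e-10, 2.98e-05 and 4.30e-16. In the synthesis list 2 fell without any 1 of the E14.5 arrays, E15.5 replicate 1, E15.5 replicate 3 or E16.5 replicate 1. In the TCA cycle, of 23 measured members, 22 rose and 0 fell (23 and 0 adjusted over the list alone). In oxidative phosphorylation, of 48 measured members, 45 rose and 1 fell (45 and 1 adjusted over the list alone). Their relative medians were 1.49 and 1.16, with camera adjusted p-values of 2.22e-16 and 7.41e-20. In glycogen synthesis, of 14 measured members, 9 rose and 3 fell (10 and 3 adjusted over the list alone) (camera adjusted p = 0.00367, adjusted p = 0.342 with an estimated correlation). In glycogen breakdown, of 13 measured members, 4 rose and 4 fell (5 and 4 adjusted over the list alone), and its median of 0.03 as deposited was -0.11 relative to all genes while its mean and camera pointed upward (camera adjusted p = 0.877). Without E14.5 replicate 1 the number that fell was 2. In glycolysis, of 31 measured members, 16 rose and 7 fell (17 and 8 adjusted over the list alone) (camera adjusted p = 0.0348, adjusted p = 0.352 with an estimated correlation), a call that ended without E16.5 replicate 1 (adjusted p = 0.0963) or E16.5 replicate 3 (0.0738). In autophagy, of 36 measured members, 18 rose and 4 fell (20 and 4 adjusted over the list alone) (camera adjusted p = 0.00277, adjusted p = 0.584 with an estimated correlation), and 1 fell without E14.5 replicate 1 or 2 and 2 without E14.5 replicate 3 or E16.5 replicate 3. In the lysosome, of 28 measured members, 15 rose and 7 fell (16 and 7 adjusted over the list alone) (camera adjusted p = 0.221). In the circadian clock, of 19 measured members, 14 rose and 2 fell (15 and 2 adjusted over the list alone) (camera adjusted p = 5.15e-04, adjusted p = 0.233 with an estimated correlation). Pdk4 and Phkg1 had log2 changes of 3.49 and -0.67.

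Among falling lists over both days, the extracellular matrix list had 1 higher and 30 lower of 32 (1 and 30 adjusted over the list alone; relative median -1.46, camera adjusted p = 1.34e-20). The progenitor list had 2 and 16 of 27 (2 and 16 adjusted over the list alone; relative median -0.63, camera adjusted p = 1.40e-08). Imprinted growth genes had 1 and 14 of 19 (1 and 15 adjusted over the list alone; relative median -1.27, camera adjusted p = 3.92e-10). Signalling genes had 3 and 23 of 32 (3 and 23 adjusted over the list alone; camera adjusted p = 4.71e-11, adjusted p = 0.0501 with an estimated correlation). Cell cycle genes had 2 and 32 of 40 (3 and 34 adjusted over the list alone; camera adjusted p = 9.40e-13, adjusted p = 0.245 with an estimated correlation), with cyclin Ccnd2 at -1.18. The skeletal muscle list had 0 and 30 of 32 (0 and 30 adjusted over the list alone; relative median -1.53, camera adjusted p = 4.96e-19, adjusted p = 0.0592 with an estimated correlation), and 0 and 29 without E16.5 replicate 2. Leukocytes had 5 and 10 of 24 (5 and 12 adjusted over the list alone; camera adjusted p = 0.0126, adjusted p = 0.583 with an estimated correlation, and 0.0523 with quantile normalization). Neurons and Schwann cells had 2 and 7 of 20 (2 and 7 adjusted over the list alone; camera adjusted p = 0.00687, adjusted p = 0.342 with an estimated correlation). For hormone receptors, of 26 measured members, 12 rose and 4 fell (12 and 4 adjusted over the list alone) (camera adjusted p = 0.109). For white and beige markers, of 15 measured members, 5 rose and 6 fell (5 and 6 adjusted over the list alone) (camera adjusted p = 0.573, downward, while median and mean lay above 0 as deposited). For endothelium, of 22 measured members, 7 rose and 3 fell (7 and 3 adjusted over the list alone) (camera adjusted p = 0.877), with 3 rising without E14.5 replicate 3. Mural cells gave 5 and 6 of 12, erythroid cells 5 and 5 of 18, cartilage and bone 4 and 8 of 24, epidermis 4 and 0 of 16, and liver 3 and 0 of 14. Adjusted over the list alone these were 5 and 6, 6 and 5, 5 and 9, 4 and 0, and 2 and 0, and their camera adjusted p-values were 0.345, 0.443, 0.159, 0.713 and 0.221. In the liver list 1 rose without E14.5 replicate 2. The mean of the mural list lay above 0 as deposited, while its median lay below 0 and camera placed it downward.

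The fourth comparison tests whether a gene changed differently on the second day than on the first. The heat-producing genes Ucp1 and Cox8b rose more on the second day (differences of 2.64 ± 0.22 and 2.66 ± 0.22, limma adjusted p = 1.17e-04 and 1.28e-04), and Scd1, which fell and then rose, differed by 4.32 ± 0.20. Dio2 had a difference of 3.11 ± 0.29, but its means of 3.95 ± 0.11 (SD) at E14.5 and 4.15 ± 0.15 at E15.5 lay below the 95th percentile of the receptor genes, so its first-day change was not resolved. Cox7a1, Cidec and Plin1 rose more on the first day (differences -3.37 ± 0.17, -4.02 ± 0.14 and -3.25 ± 0.16). Cell cycle genes had a more negative second day in 33 of 40 members (39 adjusted over the list alone) and a more positive one in 1 (camera adjusted p = 2.11e-44, adjusted p = 0.071 with an estimated correlation), with Birc5 at -1.29 ± 0.14. Without E15.5 replicate 1, 2 or 3 those with a more negative second day were 13, 12 and 13. Skeletal muscle genes had a more positive second day in 18 of 32 members (24 adjusted over the list alone; camera adjusted p = 6.52e-18, adjusted p = 0.11 with an estimated correlation), 11 without any 1 of the E14.5 arrays or E15.5 replicate 1, 3 without E15.5 replicate 2 and 6 without E15.5 replicate 3. General adipocyte genes had a more negative second day in 17 of 29 (21 adjusted over the list alone; camera adjusted p = 1.62e-23) and 11 without E15.5 replicate 3. In all, 1610 genes differed, 864 with a more positive and 746 with a more negative second day. The count was 988 without E14.5 replicate 2, 1041 without E14.5 replicate 3, 721, 606 and 669 without E15.5 replicate 1, 2 and 3, and 3361 without E16.5 replicate 2.

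The changes of the 2 days were compared gene by gene. Of the genes called on each day, 1748 rose on both, against 313.8 for independent lists, and 1327 fell on both, against 293.7. Cidea, Adig, Ppargc1a and Gbe1 rose on both days, and Sox9, Pdgfra, Fbn2 and Sfrp2 fell on both. Another 176 rose and then fell, against 237.1, and 98 fell and then rose, against 388.7. Across genes, which are not independent replicates, the log2 changes of the days had a correlation of 0.544 and a covariance of 0.0776. In simulated data without effects these were -0.501 and -0.0091. Genes called on both days numbered 3349, and 0 in the simulations. Data without effects yield almost no calls on either day, so that 0 says nothing about agreement between the days. The E15.5 arrays enter both days with opposite sign, so they pull the correlation and the covariance down, while both lay above 0 here.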

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

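The tests of E16.5 replicate 2 against low-signal values and against stage, both tests of the muscle genes and both tests of Xist were chosen after their results had been seen, and the test of other cell types on that array and the counts of other splits were chosen before. Groups of 3 arrays are too small for a search for single distant arrays, so what follows are differences between the days, found by testing the second-day minus the first-day change with limma, and 3 patterns among the arrays and gene lists. The contrast called 1610 genes.

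Of the 203 genes named, 103 differed between the days, against 1610 of all 30915 genes. Many were named for a large change or a small p in 1 comparison, so this share partly follows from the choice. Of the 103, 42 had a more positive and 61 a more negative second day, given here as the difference in log2 change. The largest such values were Scd1 4.32, Tmem45b 3.51, Dio2 3.11, Corin 3.09, Cpn2 2.74, B4galnt4 2.69, Slc25a35 2.68, Cox8b 2.66, Ucp1 2.64, Frzb 2.55, Rimklb 2.35, Dcc 2.29, Cemip 2.19 and Mybph 1.49. Next in size were Cd24a 1.39, Ngfr 1.33, Crabp2 1.29, Erbb3 1.28, Clstn2 1.27, Chrnd 1.24, Nefl 1.23, Tmem8c 1.19, Vwf 1.19, Slc25a20 1.16, Ppp1r3b 1.09, Cideb 1.06, Myod1 1.05 and Fgfr4 0.99. Smaller positive differences were those of Thbs1 0.93, Myog 0.93, Dkk2 0.90, Pygm 0.89, Stbd1 0.89, Tnc 0.86, Epm2a 0.84, Itgam 0.79, Ugp2 0.76, Ppp1r3c 0.76, Adra1a 0.65, Acta2 0.59, Ccnd1 0.55 and Agpat3 0.53. The most negative values were Cidec -4.02, Cox7a1 -3.37, Chchd10 -3.37, Plin1 -3.25, Mrap -3.23, Klb -3.10, Slc36a2 -2.96, Acvr1c -2.92, Aqp7 -2.67, Pnpla2 -2.63, Mlxipl -2.49, Plin4 -2.42, Kcnk3 -2.26 and Cth -2.26. After these came Adipoq -2.08, Chac1 -1.97, Nnat -1.86, Alpl -1.74, Pcx -1.72, Ppargc1a -1.65, Pex11a -1.63, Acsl1 -1.63, Cidea -1.58, Tmem178 -1.58, Tfrc -1.57, Retn -1.49, Hbb-y -1.48 and Rgs5 -1.47. Smaller negative differences belonged to Mthfd2 -1.44, Sesn2 -1.42, Phex -1.30, Birc5 -1.29, Cdc6 -1.28, Rrm2 -1.18, Idh3a -1.12, Lep -1.09, Fmod -1.08, Acadm -1.07, Acadl -0.96, Has2 -0.96, Mcm2 -0.95 and Asns -0.95. Others below 0 were Pgam1 -0.93, Gas5 -0.91, Mcm3 -0.91, Lpin1 -0.88, Cebpa -0.87, Adig -0.86, Ppp1r3d -0.86, Fabp4 -0.85, Cenpe -0.85, Dgat2 -0.83, Cited1 -0.81, E2f2 -0.74, Pdhb -0.73 and Cyc1 -0.72. Closest to 0 were Mki67 -0.71, Dld -0.65, Uqcrfs1 -0.64, Ccnd2 -0.62 and Ndufb9 -0.56. Dio2 and Cpn2 on the first day and Dcc on the second had means below the 95th percentile of the receptor genes at both stages, so their change on that day was not resolved. Those of B4galnt4, Cemip, Rimklb, Adig, Acvr1c and Lep lay below it at 1 stage, so their changes to or from that stage are understated.

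By camera at the preset correlation, 13 lists differed between the days, given with the median difference in log2 change as deposited and then relative to the median of all genes: general adipocyte differentiation (-0.86 and -0.94, adjusted p = 1.62e-23), autophagy core machinery (0.15 and 0.07, adjusted p = 0.0497), lipid droplet proteins (-0.37 and -0.45, adjusted p = 2.89e-08), fatty acid and triglyceride synthesis (0.43 and 0.35, adjusted p = 0.0329), mitochondrial fatty acid oxidation (-0.43 and -0.51, adjusted p = 1.70e-07), TCA cycle (-0.42 and -0.50, adjusted p = 8.22e-18), oxidative phosphorylation (-0.26 and -0.34, adjusted p = 7.05e-11), cell cycle and proliferation (-0.85 and -0.93, adjusted p = 2.11e-44), Wnt, BMP and hedgehog signalling (0.23 and 0.14, adjusted p = 4.48e-04), skeletal muscle (0.83 and 0.75, adjusted p = 6.52e-18), endothelium (0.18 and 0.10, adjusted p = 0.0213), macrophage and other leukocyte (0.40 and 0.32, adjusted p = 0.0102) and neuron and Schwann cell (0.36 and 0.28, adjusted p = 4.30e-04). With an estimated correlation the adipocyte list (0.0357), the TCA cycle (0.0167) and oxidative phosphorylation (0.0167) had an adjusted p under the threshold, and for the other lists it was 0.0519 or more.

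The 10 ways to split 6 arrays into groups of 3 are too few for a share under 0.05. The real split gave 6275 genes for E15.5 against E14.5, 6076 for E16.5 against E15.5 and 12171 for E16.5 against E14.5, each matched by 1 split (the real one), and the highest of the others gave 0 in each comparison. For the F-test over 3 stages, 1 of 100 splits of the 9 arrays, the real one, gave as many as 10849 genes and the highest other gave 5491, so chance could be excluded. For the difference between the days, 6 of 100 splits gave at least 1610 genes and the highest other gave 11122. Of the other splits that gave as many, 4 kept 1 stage whole and 1, the highest, held the 3 stages in another order, so they carry the differences between stages into this contrast. The 88 splits that kept no stage whole gave 0 genes, and the splits do not settle whether chance can be excluded for that count.

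E16.5 replicate 2 stood apart from the other arrays of its stage, with r of 0.992 to 0.993 against 0.997 between the others. Its values lay higher throughout, by a median of 0.365 in the dimmest of 4 equal groups of genes and 0.192 in the brightest, and a raised background or scaling may contribute and stays open, since the dimmest group did not reach 3 times the brightest, as the test asked. The deposited values did not decide whether that preparation was further along in development. The genes that changed at least 2-fold from E15.5 to E16.5 without that array went both ways, as values that lie higher throughout would. Median progress along the change was 0.106 (bootstrap interval 0.088 to 0.136) in 376 that rose and -0.173 (-0.207 to -0.134) in 264 that fell. Less genes of the same brightness it was -0.056 (-0.074 to -0.036) and 0.0071 (-0.028 to 0.041), so neither set then lay above 0 beyond its interval. A preparation further along would put both sets above 0, so these values argue against it for these genes on this array. The intervals resample genes of 1 array and do not measure a spread between preparations. Cells of another type stay open too, since no list rose above genes of the same brightness by more than 0.09 (erythroid) while skeletal muscle lay at -0.454, the reverse of added cells. A difference between pools of embryos of the same stage was not tested.

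The skeletal muscle list had a mean log2 change, as deposited, of -1.09 on the first day and -0.26 on the second, and the labels give no muscle in the samples. A smaller share of muscle tissue and nothing else would move all muscle genes alike. On the second day 7 genes of myogenic regulation or fusion changed by -0.378 (SE 0.083), and 8 genes of adult muscle by 0.209 (SE 0.108). The regulation set less the adult set gave -0.587 (SE 0.064), after -0.749 (SE 0.047) on the first day. These values argue against a smaller share alone only if both sets are expressed in muscle alone, which was not tested. A rise of an adult muscle gene in brown adipocytes would widen the difference. Dilution of every other cell type by growing adipocytes is argued against as the whole cause, because on the first day the muscle list fell by more than the endothelium list, with a difference of -1.04 (SE 0.077). A change in dissection between stages combined with maturation of the muscle may remain, as may loss of myogenic expression in cells of the BAT itself, and neither was tested.

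Xist, the transcript that silences an X chromosome in female cells, had log2 values of 11.5, 10.9 and 11.2 at E14.5, 10.2, 5.02 and 10.9 at E15.5, and 8.95, 9.43 and 10.3 at E16.5. Pools with different numbers of male embryos may account for this, as Xist correlated with the mean of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) over 9 arrays at Pearson r = -0.750 (exact permutation p = 0.0019, adjusted 0.0058 over 3 tests) and Spearman rho = -0.812 (exact permutation p = 0.011, adjusted 0.0165). Without E15.5 replicate 2 and E16.5 replicate 1, the arrays farthest from the median, r was -0.669 over 7 arrays (exact permutation p = 0.0992) and did not pass. Whether the relation rests on those arrays or fewer arrays ended the call is open. Permutations crossed stages, so these p-values include stage differences. Deviations from stage means gave r = -0.636, untested. A wrong stage label is argued against, because 0 of the 9 arrays correlated best with one of another stage. Embryo sex was not given in the sources used here.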

How the results depend on the processing

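The covariate of Y-linked genes and the fit with quantile normalization without E16.5 replicate 2 were chosen after seeing the data. For the 203 named genes in 3 stage comparisons, 10752 of 10944 values kept their side of the threshold, with the same direction where they were called. Another 117 lost and 75 gained a call, and 0 with a call in either fit reversed. Directions of values without a call in both fits were not compared. For the 29 lists, 1522 of 1563 values under other fits kept their side in the same sense. Of the rest, 16 lost and 25 gained a call and 0 reversed. With an estimated correlation 27 of 87 list results lost their call. Moves of list counts between 0, 1 and 2 members are not listed. With fry, which asks whether a list's genes move one way and does not compare them with other genes, 3 lost and 10 gained one. The number of genes changed from E14.5 to E15.5 was 4880 to 9053 when 1 array was left out, 10026 with array weights and 1224 with a minimum change of 2-fold. From E15.5 to E16.5 it was 4378 to 7777 and 654 at 2-fold, and from E14.5 to E16.5 it was 9730 to 13299 and 3231. The F-test gave 8988 to 12675. Of these counts, that of genes that differed between the days moved most when 1 array was left out, to values from 606 to 3361. It was 2626 with quantile normalization, 2502 without genes below the median brightness, 3825 with array weights, 906 with the Y-linked covariate, 3474 with quantile normalization without E16.5 replicate 2, and 692 at 2-fold. The weight of E16.5 replicate 2 was 0.0847. With the Y-linked covariate the other counts were 4793 for the first day, 5703 for the second, 10023 for both days and 9507 for the F-test. The mean of the Y-linked genes was 6.77 to 7.62 on the E14.5 arrays and 7.59 to 8.58 on the E15.5 arrays. The covariate and the first-day comparison were therefore partly confounded. Fewer genes were tested in the brightness filter and a smaller set is counted at 2-fold, by construction, and for the others the cause was not tested. With the replicate number as a block, the counts were 6074, 5817, 12152, 1364 for the difference and 10738 for the F-test, and the numbers did not pair the arrays, since same-numbered arrays had deviations correlated at -0.134 to 0.10. All transcript clusters, and the mean of clusters per gene, could not be run because the table held 1 value per symbol. The 95th percentile of the receptor genes averaged 4.28, 4.38 and 4.54 at E14.5, E15.5 and E16.5. Of the named genes, 14 had a mean below it at 1 or more stages and 2, Gys2 and S100a9, at all 3. A change between 2 stages below it was not resolved over background, and one with 1 stage below it is understated.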

Other observations

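The tests of the cholesterol synthesis list and the ATF4 list were chosen before their results were seen, while the groups of genes by symbol and the genes Cth and Chac1 were chosen after their values were seen. The camera p-values of the groups by symbol therefore describe those groups and are not independent tests of their rise or fall.

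Further groups of genes rose with the mitochondrial lists by the preset test. Of 77 mitochondrial ribosomal protein genes, 70 rose and 0 fell on the first day, 53 and 0 on the second, and 74 and 0 over both days (relative median 0.95, camera adjusted p = 4.59e-24, adjusted p = 0.0956 with an estimated correlation). All 9 genes with Coq symbols, most of which act in coenzyme Q synthesis, rose over both days (relative median 1.55, camera adjusted p = 2.37e-07, adjusted p = 0.0956 with an estimated correlation), as did 13 of 14 genes with Timm symbols, of import across the inner mitochondrial membrane (relative median 0.92, camera adjusted p = 7.19e-07, adjusted p = 0.0956 with an estimated correlation) and 15 of 17 genes with Pex symbols, most of which act in peroxisome biogenesis (relative median 0.80, camera adjusted p = 5.02e-08, adjusted p = 0.0643 with an estimated correlation). Pex11a, which divides peroxisomes, rose by 2.71 ± 0.09 on the first day and 1.08 ± 0.09 on the second. Cytosolic ribosomal protein genes, which serve translation outside mitochondria, had over both days 8 higher and 23 lower of 83 (camera adjusted p = 0.00286, adjusted p = 0.54 with an estimated correlation).

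Other groups fell by the preset test. Of 9 genes whose symbols begin with Igf and a digit of 1 or 2, 8 fell over both days (relative median -1.40, camera adjusted p = 7.29e-08, adjusted p = 0.0643 with an estimated correlation), among them the RNA-binding Igf2bp1 (-2.54 ± 0.10) and Igf2bp2 (-2.22 ± 0.10). Of 19 Adamts proteases, which trim the matrix, 16 fell (relative median -1.22, camera adjusted p = 2.82e-11, adjusted p = 0.0643 with an estimated correlation), and of 15 genes with Snhg symbols (small nucleolar RNA hosts) 9 fell (relative median -0.70, camera adjusted p = 1.30e-04, adjusted p = 0.172 with an estimated correlation). Of 20 genes with Nup symbols (nucleoporins) 17 fell on the second day against 2 on the first (second day camera adjusted p = 4.08e-16, adjusted p = 0.0763 with an estimated correlation; second day minus first day 7.06e-13 and 0.142).

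Cth and Chac1, which act in cysteine and glutathione metabolism, were higher at E15.5 than on either side (log2 changes 1.38 ± 0.10 then -0.88 ± 0.10, and 1.05 ± 0.11 then -0.92 ± 0.11). A hypothesis is an amino acid stress response driven by ATF4 that peaks at E15.5. In a list of 26 known ATF4 targets that holds neither gene, the median second-day minus first-day change was -0.583 as deposited and -0.66 relative to all genes (camera adjusted p = 6.73e-17, adjusted p = 0.13 with an estimated correlation), and 17 of 26 had their highest mean at E15.5, with 9 rising on the first day and 11 falling on the second. The log2 changes on the successive days were 0.84 and -0.11 for Asns, where the second did not pass, 0.91 and -0.51 for Sesn2, and 0.46 and -0.98 for Mthfd2. The values go with the hypothesis, but the shape was not particular to ATF4 targets. Genes with Nup symbols had a median difference of -0.583 as deposited, with 10 of 20 highest at E15.5. The cell cycle list had a median difference of -0.85. Genes with Pex and Snhg symbols differed, with 1 of 17 and 1 of 15 highest at E15.5. The ATF4 call is also lost with the estimated correlation, and the hypothesis was found and tested on the same arrays.

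Scd1 was lower at E15.5 than on either side, and a shared sterol regulatory input was tested as a hypothesis. In a list of 23 measured cholesterol synthesis genes, the median second-day minus first-day change was 0.342 as deposited and 0.26 relative to all genes (camera adjusted p = 6.69e-04, adjusted p = 0.407 with an estimated correlation), but 6 of 23 had their lowest mean at E15.5, fewer than the test required, so the question stays open.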
